A study of Rattus norvegicus with 8 samples.

How the data were processed

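Hepatocytes were isolated by enzymatic perfusion from 4 rats, per the labels, with a viability above 85%, plated at 90% confluency on collagen, held for 4 h in medium with albumin and then overnight without it. Cultures were then exposed to cadmium chloride at 4 µM or to medium alone for 3 h, and biotinylated cRNA was made from 8 µg of total RNA. The labels give 4 control and 4 cadmium samples and tie each number to a rat, so the 4 samples of a group come from separate animals.

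The deposited table of the whole series holds 1 linear intensity (signal) per probe set and array. The authors used MAS5, per the submitters' processing notes, which give no version; the scaling target, probe mask and detection calls are not given in the sources used here. The values themselves show the scaling: the mean without the lowest and highest 2% of probe sets was about 500 on each array, while medians and quartiles differed. Other deposited files, 1 per array, hold the settings of the array run and no expression values, per the file headers. They were used only to define batches: 2 chip lots (rats 1 and 2 on lot 2, rats 3 and 4 on lot 1), 4 scan days with the 2 arrays of 1 rat each, and 2 modules of 1 fluidics station, 1 for controls and the other for cadmium arrays. Between 64.4% and 66.7% of probe sets had a signal of at least 100 on an array. MAS5 summarizes each array alone, so values at the dim end are noisy, and scaling to a common trimmed mean moves all other probe sets slightly down where some bright ones rise.

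The table has 15923 probe sets, of which 57 controls were left out of the tests. Probe sets were named from the platform annotation with symbols updated by gene number to the RefSeq annotation of the assembly GRCr8, used for names only: of 15866 probe sets, 12783 had 1 symbol (12748 through the gene number, 2 through an accession and 33 with the symbol kept), 312 had several and 2771 had none here. Probe sets with several symbols were tested but not named, so Hspa1b, Mt1a and G6pc1 have no value of their own. For a gene with several probe sets, the one with the highest mean log2 value over all 8 arrays stood for the gene, giving 10411 genes before and 7099 after the filter. Array probe sets carry no coordinates in the sources used here.

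Signals were used as log2(signal + 1), and the 40% of probe sets with the lowest mean over all 8 arrays (signal under 118) were left out, leaving 9519. No further normalization was applied. The pseudocount understates changes of dim genes. Cadmium was compared with control by lmFit and eBayes with a variance trend in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Gene lists with at least 5 tested members (26 of 29) were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with the correlation estimated. Lists, tests, the naming rule and the alternative settings were fixed before the data were examined. Differences between rats were tested with the moderated F statistic, with cadmium as a term. RNA quality ratios and array medians were compared with exact permutation tests over the 70 assignments of arrays to groups.

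Genes are named by 1 rule: the 10 largest rises and 10 largest falls among genes past the threshold that moved the same way in 4 of 4 rats; up to 3 such members of each list, or the 2 brightest where none passed; and a fixed set of cadmium and stress genes, which holds Mt1, Mt2A, Hmox1, Hspa1a, Fos, Jun, Myc, Atf3, Ddit3, Gclc, Txnrd1, Slc30a1, Pck1 and Cyp7a1. Genes named outside this rule are marked as such.

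The fit reported first has no term for the rat, since no source used here states a paired test. Its errors thus hold the spread between rats, and its counts and the ranking of genes leave the pairing out. With the rat as a block, 171 probe sets passed that did not pass without it, and 17 passed only without it. The numbers pair the samples, because both samples of a number come from the same rat, per the labels. As a check, deviations from the group means correlated across probe sets at 0.35, 0.251, 0.475 and 0.196 between the 2 arrays of rats 1 to 4, against at most -0.008 between arrays of different rats. The fit with the rat as a replicate block was fixed beforehand as an alternative. Other alternatives were a pseudocount of 32, no filter or a filter of 60%, quantile normalization, median centring, no variance trend, the chip lot as a block, a 1.5-fold minimum, an adjusted threshold of 0.1, the mean of a gene's probe sets, and each array or each rat left out. Fits within each chip lot were added after the array settings were read. No 2 arrays were duplicates (correlation of log2 signals at most 0.971).

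The fits were tested on simulated data with the means and spreads of the real arrays (9519 probe sets, cadmium against control). Of 50 probe sets changed at each size, 20% were recovered at a log2 change of 0.5, 78% at 1, 98% at 2 and 98% at 3; 8 unchanged probe sets were called, and 0 when nothing was changed. The list test called the 1 list that was shifted by 0.5 and no other. Probe sets were drawn independently and, outside the rat test, without a rat effect. The simulation thus does not show how often the list test errs where genes of a list move together. The rat test recovered 59.5% of 200 probe sets with a simulated rat effect. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).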

Results

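Gene expression was measured in primary rat hepatocytes, the parenchymal cells of the liver, taken from 4 rats and kept in culture. From each rat, 1 culture received cadmium chloride, a soluble salt of a toxic metal, at 4 µM for 3 h, and 1 received culture medium alone. The 4 control and 4 cadmium RNA samples were each hybridized to 1 rat oligonucleotide array (Affymetrix RAE230A), on which a gene is read by 1 or more probe sets. The title of the series puts the question as the response to a low dose and a short exposure. The median signal of an array lay between 191.7 and 197.0 in controls (194 ± 2.30, mean ± SD, n = 4) and between 179.7 and 186.1 after cadmium (184 ± 2.83, n = 4; exact two-sided permutation p = 0.0286, the smallest value that the 70 assignments allow). Arrays have no read depth, and their number limits the precision.

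Among genes read on their brightest probe set, the largest rises after 3 h of cadmium were in Hspa1a, Egr1 and Hmox1. These are members of the heat shock, immediate early and antioxidant lists, in that order. Hspa1a, the inducible chaperone of the HSP70 family, rose from a signal of 416 ± 111 to 24762 ± 2726 (mean ± SD, n = 4 per group), a log2 change of 5.92 ± 0.17 (SE; limma adjusted p = 9.12e-09). Egr1, an immediate early transcription factor, rose from 257 ± 47.7 to 12988 ± 1790, a log2 change of 5.66 ± 0.15 (adjusted p = 5.68e-09). Hmox1, the haem-degrading enzyme haem oxygenase 1, rose from 664 ± 194 to 19720 ± 1336, a log2 change of 4.93 ± 0.17 (adjusted p = 2.53e-08). The other genes among the 10 largest rises were the HSP40 co-chaperones Dnajb1 (log2 change 4.56) and Dnaja4 (3.65), the zinc finger protein Zfand2a (3.99), the stress transcription factor Atf3 (3.84), the secreted growth factor family member Gdf15 (2.95), the HSP110 chaperone Hsph1 (2.93) and the co-chaperone Bag3 (2.88). Their adjusted p lay between 2.52e-08 and 1.78e-05, and each rose in 4 of 4 rats.

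Falls of genes with a symbol were smaller, and the 5 probe sets that fell at least 4-fold have no symbol here. Among genes read on their brightest probe set the largest fall was in Zfc3h1, a zinc finger protein of nuclear RNA decay, from 809 ± 147 to 201 ± 26.1, a log2 change of -1.997 ± 0.16 (adjusted p = 3.58e-05). Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, had a log2 change of -1.84 ± 0.39 (adjusted p = 0.0276), with single rats between -0.29 and -3.06. Arrdc3 (-1.63), the NF-kB inhibitor gene Nfkbia (-1.46), the O-GlcNAc transferase Ogt (-1.35), the basement membrane proteoglycans Agrn (-1.18) and Hspg2 (-1.10), Nhlrc2 (-1.16), Epm2aip1 (-1.15) and the nuclear pore gene Nup210 (-1.14) made up the rest of the 10 largest falls. Each of the 10 fell in 4 of 4 rats. The ranking holds only genes that passed in the fit without the block. The adjusted p rose past 0.05 for Cyp1a1, Nfkbia, Nup210 and Hspg2 when 1 array was left out, to 0.0871, 0.0862, 0.0946 and 0.0535, in each case without control replicate 3. Other single arrays whose loss ended a call were cadmium replicates 1, 3 and 4 for Cyp1a1, control replicates 1, 2 and 4 and cadmium replicate 1 for Nfkbia, and control replicates 1 and 4 and cadmium replicates 1, 2 and 3 for Nup210. The call of Nup210 also ended without the filter. All 4 rats entered the paired fit with the replicate block, where the limma adjusted p was 0.0273 for Cyp1a1, 0.00563 for Nfkbia, 0.024 for Nup210 and 0.01495 for Hspg2.

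**Figure D1:**
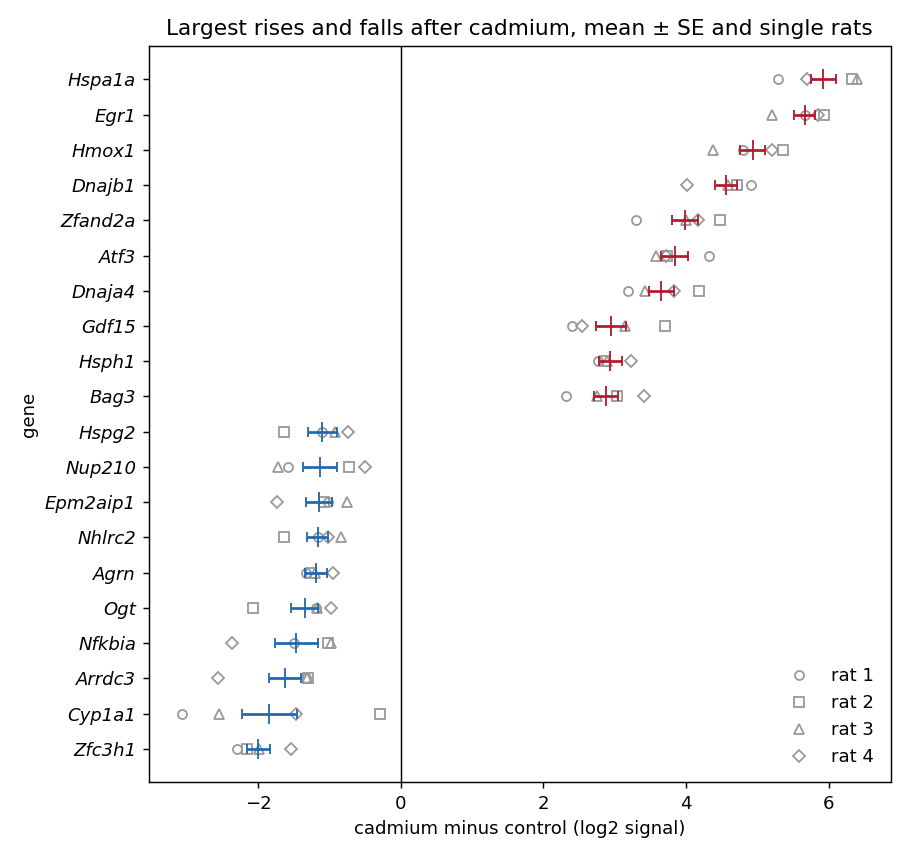
Log2 change in signal (cadmium minus control, x axis) of the 10 genes with the largest rise and the 10 with the largest fall (y axis). Only genes that passed in the fit without the block were ranked. Vertical ticks with bars are the mean ± SE of the fit (red, higher; blue, lower; 4 rats), and open symbols are the differences within each rat. The means run from -1.997 in Zfc3h1 to 5.92 in Hspa1a, and no rat crosses 0.

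Over the whole array, 336 of 9519 tested probe sets changed at an adjusted p under 0.05, 200 higher and 136 lower, and 1566 had an unadjusted p under 0.05. Counting 1 probe set per gene, 145 genes rose and 93 fell. At least 2-fold changes were seen in 107 rises and 29 falls, and at least 4-fold changes in 24 rises and 5 falls. All 336 probe sets moved the same way in 4 of 4 rats. In the paired fit, with the rat as a replicate block, 272 probe sets were higher and 218 lower (194 and 157 genes), 319 of them shared with the fit without the block. Falls were the less certain part. Higher probe sets made up 59.5% of the calls, against 70.6% after quantile normalization (209 higher, 87 lower) and 73.2% after centring each array on its median (229 higher, 84 lower). Counts also depended on single arrays. Genes lower numbered 47, 36, 35 and 31 without control replicates 1 to 4, and 42, 39 and 54 without cadmium replicates 1 to 3, against 90 without cadmium replicate 4. Genes higher numbered 86, 90 and 93 without control replicates 2, 3 and 4 and 85 without cadmium replicate 2. With the chip lot as a block, 200 probe sets were higher and 150 lower. Within lot 1 (2 rats) the counts were 40 and 7, and within lot 2 (2 rats) 75 and 19.

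In the heat shock and chaperone list, 11 of 31 tested genes rose and none fell (16 rose when adjusted over the list alone), and the median log2 change was 0.30. Beside Hspa1a, Dnajb1, Dnaja4, Hsph1 and Bag3, the genes that rose were the small heat shock protein gene Hspb1, Dnaja1, Chordc1, Dnajb4, the co-chaperone Stip1 and the mitochondrial chaperonin partner Hspe1, which were listed here after their values were seen. In the paired fit with the replicate block, 13 rose. The list was higher than the other genes in the camera test of limma (adjusted p = 2.27e-25; with an estimated correlation, adjusted p = 0.0384). Its median was 0.41 within chip lot 1 (camera adjusted p = 4.77e-22) and 0.28 within lot 2 (camera adjusted p = 9.37e-19). The p-values within lots, here and for the lists below, rest on 2 rats each and on the preset correlation. They overstate the evidence where genes of a list move together. Hspa1a is nearly identical in sequence to Hspa1b, which had no probe set of its own here, so the signal was not resolved between them.

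The immediate early list, genes that respond to signals before new protein is made, had 14 of 36 tested genes higher and none lower (19 higher and 1 lower when adjusted over the list alone; 16 higher and 1 lower in the paired fit with the replicate block), with a median log2 change of 0.51. Next to Egr1, the AP-1 subunit gene Fosl1 rose by 2.68 ± 0.15 (240 ± 39.1 to 1542 ± 239; adjusted p = 2.14e-06) and Jun by 2.11 ± 0.16 (1913 ± 408 to 8178 ± 1076; adjusted p = 2.31e-05). Egr2 had a log2 change of 2.43 ± 0.22 (adjusted p = 0.000104), but its control signal of 83 ± 24.9 lay below the signal of 118 that set the filter for dim probe sets. Myc rose by 0.95 ± 0.17 (adjusted p = 0.0114). Both probe sets of Fos lay below that filter. Without the filter they gave log2 changes of 0.34 ± 0.55 (adjusted p = 0.874) and 3.44 ± 0.74 (adjusted p = 0.0493), the latter from a signal of 13.3 ± 15.5 to 106 ± 54.7. The list was higher in the camera test (adjusted p = 4.55e-19; with an estimated correlation, adjusted p = 0.0384), and its median was 0.81 within chip lot 1 (adjusted p = 3.28e-18) and 0.42 within lot 2 (adjusted p = 8.45e-12).

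Among antioxidant genes and targets of the transcription factor NRF2, 6 of 30 tested genes rose and 1 fell (8 and 2 when adjusted over the list alone; 7 and 2 in the paired fit with the replicate block). After Hmox1, the largest rises were in Osgin1 (1.73 ± 0.11; adjusted p = 6.43e-06) and the sulfiredoxin gene Srxn1 (1.33 ± 0.12; adjusted p = 0.000125). The thioredoxin reductase gene Txnrd1 rose from 2475 ± 445 to 4928 ± 879, a log2 change of 0.99 ± 0.15 (adjusted p = 0.00484). Gclc, which encodes the catalytic subunit of the enzyme that starts glutathione synthesis, had a log2 change of 0.63 ± 0.17 and did not pass (adjusted p = 0.0748). It passed in the paired fit with the replicate block (adjusted p = 0.00505), and a dimmer probe set of the same gene gave 0.84 ± 0.19 (adjusted p = 0.0384). The gene that fell was Nfe2l2, which encodes NRF2 itself, named after its value was seen. The list was higher in the camera test (adjusted p = 3.33e-05; with an estimated correlation, adjusted p = 0.0384). Its median was 0.06, and it was 0.02 within chip lot 1 (adjusted p = 0.00226) and 0.13 within lot 2 (adjusted p = 0.000115).

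Metallothioneins bind cadmium and zinc. Mt2A rose from 7345 ± 2430 to 13666 ± 3398, a log2 change of 0.92 ± 0.22 (adjusted p = 0.0455). The differences in rats 1 to 4 were 0.996, 1.17, 0.005 and 1.49, so rat 3 showed almost none. Mt2A was the only gene past the threshold among 16 tested genes of metal binding and zinc transport (1 when adjusted over the list alone). The call was lost after quantile normalization, without the filter, without a variance trend and when any of 7 arrays was left out, with an adjusted p up to 0.127, without control replicate 2 (each array but control replicate 3). Slc30a1, the zinc exporter ZnT1, had a log2 change of 0.53 ± 0.26 (adjusted p = 0.341). Mt1 was below the filter, with signals of 59.2 ± 33.4 and 81.4 ± 47.3 (limma adjusted p = 0.908 without the filter), too dim for a precise reading. Mt1a had no probe set with its symbol alone, and probe sets with several symbols were tested but not named. The values here thus do not cover every metallothionein reading of the array. The list as a whole did not pass (camera adjusted p = 0.747; its median was -0.09 and its mean 0.01).

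Genes of the unfolded protein and integrated stress responses split. Of 37 tested genes, 6 rose and none fell (6 higher and 2 lower when adjusted over the list alone). In the paired fit with the replicate block 6 rose and 3 fell, the latter Syvn1, Eif2ak3 and Creld2 (blocked adjusted p = 0.0250, 0.0251 and 0.0409; each lower in 4 of 4 rats), named after their values were seen. Atf3 rose most, followed by Chac1, which degrades glutathione (1.87 ± 0.20; adjusted p = 0.000382), and Ppp1r15a, a phosphatase subunit that reverses eIF2-alpha phosphorylation (1.79 ± 0.16; adjusted p = 8.57e-05). The rest, listed after their values were seen, were Atf4, Trib3 and Dnajb9. Ddit3, which encodes CHOP, had a log2 change of -0.10 ± 0.19 (1783 ± 407 and 1650 ± 356; adjusted p = 0.852). The camera test placed the list higher (adjusted p = 0.0352) and its mean was 0.21, but its median was -0.04, against -0.06 over all tested probe sets. The camera test was not passed with an estimated correlation (adjusted p = 0.84) or in the paired fit with the replicate block (adjusted p = 0.171). The median was 0.04 within chip lot 1 (adjusted p = 0.0134) and -0.07 within lot 2 (adjusted p = 0.171), and the call also ended after quantile normalization and median centring (adjusted p = 0.281 and 0.0533), the latter with a median of 0.02. It ended without control replicates 2 and 3 (adjusted p = 0.108 and 0.367) and without cadmium replicates 1 and 4 (adjusted p = 0.124 and 0.55).

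The proteasome list had a small positive median, and its call depended on the correlation assumed between genes. Of 29 tested genes, 86.2% had a higher mean after cadmium and the median log2 change was 0.13, while only Psmc2, an ATPase of the regulatory particle, passed alone (5659 ± 134 to 7126 ± 418; log2 change 0.33 ± 0.08; adjusted p = 0.0436; also 1 when adjusted over the list alone). The call of Psmc2 ended after quantile normalization, without the filter, without a variance trend and when any of 7 arrays was left out (all but cadmium replicate 3; adjusted p up to 0.132, without cadmium replicate 2). The list was higher in the camera test (adjusted p = 7.35e-06), but not with an estimated correlation (adjusted p = 0.239). Its median was 0.15 within chip lot 1 (adjusted p = 5.1e-05) and 0.11 within lot 2 (adjusted p = 0.00167).

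Of 8 tested targets of p53, 2 fell and none rose (3 fell when adjusted over the list alone and 3 in the paired fit with the replicate block), with a median log2 change of -0.31. Ccng2 changed by -0.64 ± 0.14 (adjusted p = 0.0336) and Phlda3 by -0.51 ± 0.11 (adjusted p = 0.0362). Each call was lost after median centring. That of Ccng2 was also lost after quantile normalization and without the filter, and that of Phlda3 without a variance trend. Each was lost on leaving out any array but control replicate 4 and cadmium replicate 1 for Ccng2, or any but control replicate 1 for Phlda3 (adjusted p up to 0.107 and 0.105, without control replicate 3). Ccng2 is also known as a target of FOXO factors. The list was lower in the camera test (adjusted p = 0.0404), but not with an estimated correlation (adjusted p = 0.243) or in the paired fit with the replicate block (adjusted p = 0.0509), without the filter (adjusted p = 0.0851) or with the mean of a gene's probe sets (adjusted p = 0.0586). The median was -0.30 within chip lot 1 (adjusted p = 0.514) and -0.42 within lot 2 (adjusted p = 0.0117). The list did not pass without control replicates 1, 2 and 4 (adjusted p = 0.0831, 0.0551 and 0.0519) or cadmium replicates 1, 2 and 4 (adjusted p = 0.0696, 0.127 and 0.065).

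**Figure D2:**
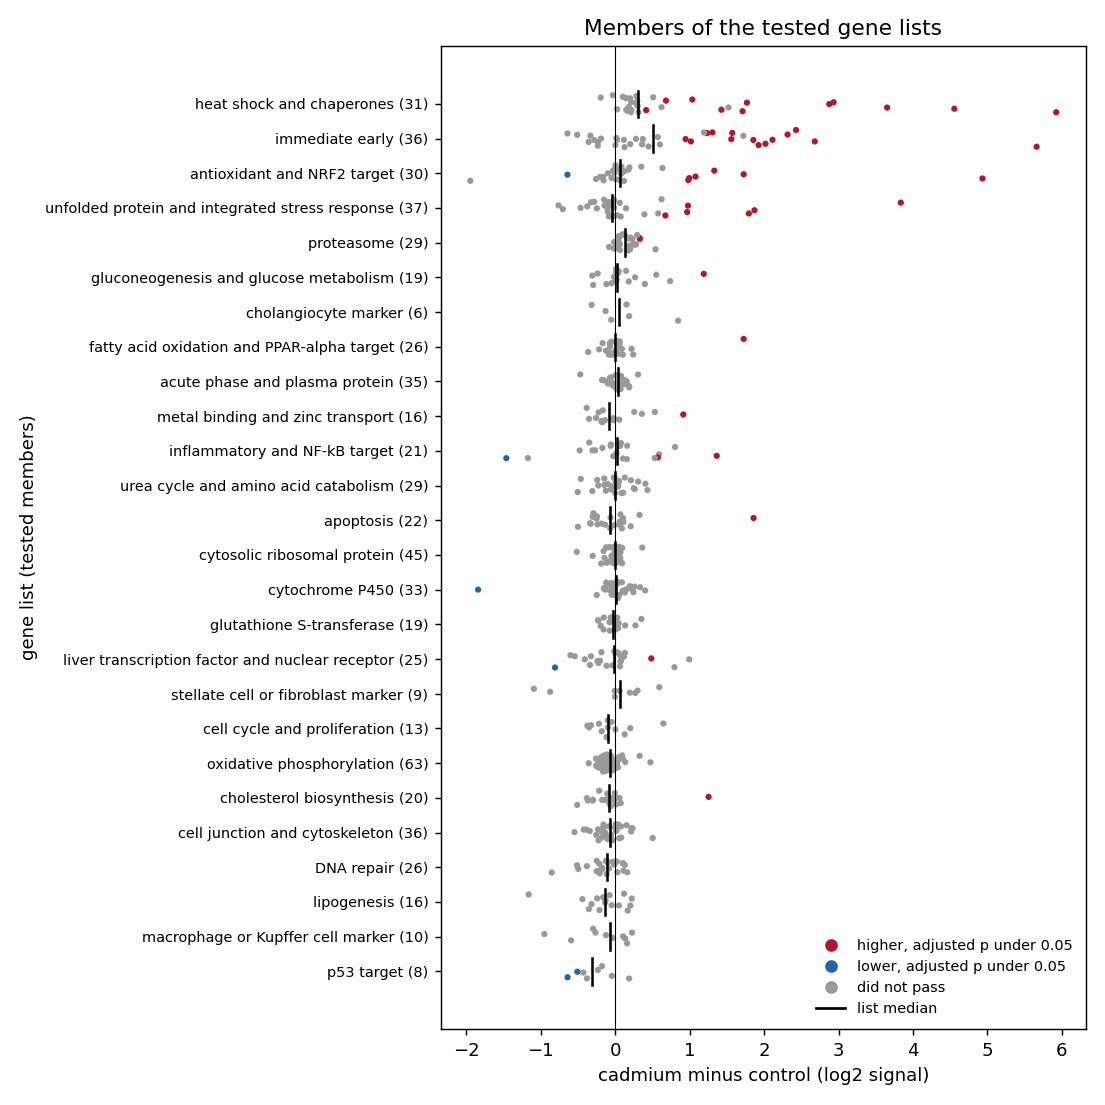
Log2 change in signal (cadmium minus control, x axis) of the members of the 26 tested gene lists (y axis, tested members in parentheses), ordered by their mean change. Each point is a gene (red, higher; blue, lower; grey, did not pass) and black ticks are list medians, which run from -0.31 in p53 targets to 0.51 in immediate early genes.

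The remaining pathway lists did not pass the camera test, and single members did in some. Among 21 inflammatory and NF-kB target genes, the chemokine gene Cxcl2 (1.36 ± 0.29; adjusted p = 0.0311) and the adhesion molecule gene Icam1 (0.57 ± 0.11; adjusted p = 0.0172) rose while Nfkbia fell, and the list had an adjusted p of 0.369. Cflar, an inhibitor of caspase-8 activation, was the only one of 22 apoptosis genes to pass (1.86 ± 0.29; adjusted p = 0.00523; list adjusted p = 0.761). The glucose transporter gene Slc2a1 rose (1.19 ± 0.15; adjusted p = 0.00115) among 19 genes of gluconeogenesis and glucose metabolism (list adjusted p = 0.112), in which Pck1, the rate-limiting enzyme of gluconeogenesis, had a log2 change of 0.27 ± 0.24 (adjusted p = 0.657). Insig1, a regulator of sterol synthesis, rose (1.25 ± 0.25; adjusted p = 0.0209) among 20 cholesterol genes (list adjusted p = 0.648), and the hormone gene Fgf21 rose (1.73 ± 0.37; adjusted p = 0.0312) among 26 genes of fatty acid oxidation (list adjusted p = 0.648). Of 25 liver transcription factors and nuclear receptors (list adjusted p = 0.747), Cebpg rose (0.48 ± 0.12; adjusted p = 0.0453) and Foxa2 fell (-0.81 ± 0.17; adjusted p = 0.0271). In 33 cytochrome P450 genes, Cyp1a1 alone passed (list adjusted p = 0.639). Adjusted over the list alone, the counts of higher and lower genes were 3 and 1 for inflammation, 1 and 1 for apoptosis, 1 and 0 for glucose metabolism, 1 and 2 for cholesterol, 1 and 0 for fatty acid oxidation, 2 and 2 for transcription factors and 0 and 1 for P450 genes. In the paired fit with the replicate block, 3 inflammatory and 2 glucose metabolism genes were higher, and 2 transcription factor genes were lower. With 1 array left out, the highest adjusted p was 0.0932 for Cxcl2 and 0.0544 for Icam1 (control replicate 2), 0.138 for Cebpg and 0.084 for Foxa2 (control replicate 3), 0.087 for Fgf21 (control replicate 4) and 0.0692 for Insig1 (cadmium replicate 2). The calls also ended without cadmium replicates 1 to 4 for Cxcl2, cadmium replicate 2 for Icam1, every other array but control replicate 4 for Cebpg. The same held for control replicates 2 and 4 and cadmium replicates 1, 2 and 4 for Foxa2, control replicates 2 and 3 and cadmium replicates 1, 2 and 4 for Fgf21, and control replicate 2 and cadmium replicates 1 and 3 for Insig1. Without the filter the calls of Cxcl2, Fgf21 and Cebpg ended, and that of Cebpg also without a variance trend and with the chip lot as a block. All these genes passed with the replicate block and all arrays. The limma adjusted p was then 0.0106 for Cxcl2, 0.0132 for Icam1, 0.0487 for Cebpg, 0.00694 for Foxa2, 0.00184 for Fgf21 and 0.000189 for Insig1. Without control replicate 3 the inflammatory list passed as higher (adjusted p = 0.0352).

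No gene passed in the lists of acute phase and plasma proteins (35 tested genes; list adjusted p = 0.383), oxidative phosphorylation (63; 0.407), cytosolic ribosomal proteins (45; 0.646), urea cycle and amino acid catabolism (29; 0.532), DNA repair (26; 0.513), glutathione S-transferases (19; 0.747), lipogenesis (16; 0.673), cell cycle (13; 0.747) and cell junction and cytoskeleton (36; 0.747). At an unadjusted p under 0.05 in limma, 1 oxidative phosphorylation gene was higher and 7 were lower, 5 DNA repair genes were lower, 2 urea cycle genes were higher and 2 lower, 2 lipogenesis and 2 cell cycle genes were lower and 1 junction gene was lower, against 0 in the other 3 lists. In the paired fit with the replicate block, 1 gene fell in each of 3 of these lists, each lower in 4 of 4 rats. Named after their values were seen, they were Fasn, the fatty acid synthase gene (-1.16 ± 0.14, SE of the blocked fit, limma adjusted p = 0.00200), the coagulation factor gene F5 (-0.47 ± 0.08, 0.0140) and the ornithine transporter gene Slc25a15 (-0.46 ± 0.10, 0.0299). Fasn fell by more than Epm2aip1, Nup210 and Hspg2. It did not pass without the block and so is not ranked among the largest falls. Without cadmium replicate 4, the lists of plasma proteins, P450 genes, glucose metabolism and the urea cycle passed as higher (adjusted p = 0.00134, 0.00387, 0.013 and 0.013), and they did so within chip lot 2 (adjusted p = 0.00167, 0.00561, 0.00561 and 0.00167). Without the pair of rat 4, in the paired fit with the replicate block, these 4 lists (adjusted p = 2.43e-05, 0.000841, 0.000841 and 0.000315) and glutathione S-transferases (adjusted p = 0.0156) passed as higher. Oxidative phosphorylation passed as lower after quantile normalization (adjusted p = 0.000272, and 0.000183 with the replicate block) and within chip lot 1 (adjusted p = 0.0269). The ribosomal protein list became lower after quantile normalization (adjusted p = 0.00602, and 0.00185 with the replicate block), and glutathione S-transferases were higher within lot 2 (adjusted p = 0.0318). Medians and the camera direction differed in sign for glutathione S-transferases (median -0.02, test higher) and transcription factors (median -0.01, test higher). The same held for metal binding and zinc transport (median -0.085, test higher). Camera compares a list with the other genes, and the median log2 change over all tested probe sets was -0.06. Medians of -0.02 and -0.01 lay above that value, and the median of metal binding and zinc transport lay below it. Abundant hepatocyte transcripts had log2 changes of 0.05 ± 0.13 in the albumin gene Alb, 0.07 ± 0.08 in Apoe and 0.04 ± 0.09 in the urea cycle gene Ass1 (adjusted p = 0.917, 0.717 and 0.873). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was below the filter (110 ± 29.5 and 131 ± 29.7; adjusted p = 0.781 without it).

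No marker of another liver cell type passed in limma without the block. In the paired fit with the replicate block the stellate cell marker Reln was lower (-1.09 ± 0.14, SE of the blocked fit; adjusted p = 0.00331), named after its value was seen. The lists for macrophages or Kupffer cells (10 tested genes), stellate cells or fibroblasts (9) and cholangiocytes (6) had camera adjusted p of 0.968, 0.747 and 0.747, and at an unadjusted p under 0.05 limma gave 0, 1 and 1 lower genes and 0 higher genes. For macrophages the median was -0.08 and the test pointed higher. Cd68 had signals of 1445 ± 748 in controls and 1691 ± 1013 after cadmium (log2 change 0.16 ± 0.46; adjusted p = 0.915), Timp1 1474 ± 259 and 1483 ± 351 (adjusted p = 0.997), and Epcam 2213 ± 415 and 2110 ± 699 (adjusted p = 0.864). Only 2 endothelial and 3 lymphocyte markers were bright enough to be tested, which is too few for a list test. The endothelial genes Egfl7 and Esam had log2 changes of 0.09 and 0.01, and the lymphocyte genes Lck and Cd247 of -0.15 and -0.19. No red blood cell marker was bright enough.

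The 2 cultures of each rat allow the spread between animals to be set beside the effect of cadmium. With cadmium in the model, 167 probe sets (134 genes) differed between the 4 rats in the moderated F test of limma at an adjusted p under 0.05, and 1492 at an unadjusted p under 0.05. The count was 87 without the filter and 36 without a variance trend. Over all tested probe sets, cadmium took 32.4% of the sum of squares with 14.3% of the degrees of freedom, the rat term 44.4% with 42.9% and the rest 23.2% with 42.9%. On equal degrees of freedom, the rat term thus took more than the rest. The 3 genes with the widest range of rat means, named after their values were seen, were Ubd, a ubiquitin-like protein gene (range 7.41 log2 units, with rat 1 low; adjusted p = 9.08e-09), and the major histocompatibility genes RT1-A (4.78, with rat 3 low; adjusted p = 2.02e-07) and RT1-CE16 (4.03, with rats 1 and 2 low; adjusted p = 2.76e-05). The first principal component (33.4% of the variance) parted cadmium from control arrays, and the next 2 held 18.4% and 16.5%. The 2 arrays of a rat were scanned on the same day and each rat on its own day, so rat and scan day cannot be told apart. Without the pair of 1 rat, between 53 and 359 probe sets differed. The count was 94 without rat 1, 92 without rat 2, 53 without rat 3 and 359 without rat 4.

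**Figure D3:**
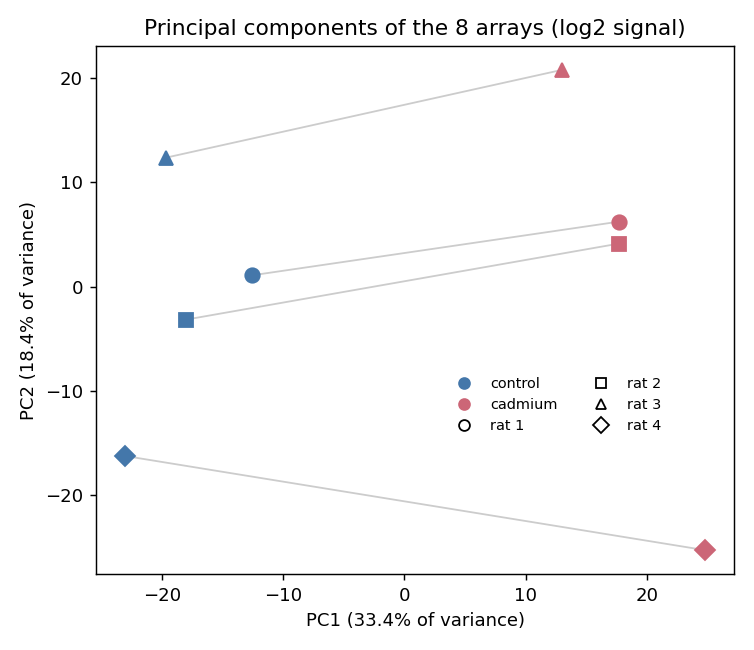
Positions of the 8 arrays on the first principal component (x axis, 33.4% of the variance) and the next (y axis, 18.4%) of the log2 signals of 9519 probe sets. Blue is control, red is cadmium, symbols are rats and grey lines join the arrays of a rat. Controls lie between -23.05 and -12.57 and cadmium arrays between 12.98 and 24.84 on the x axis.

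Signs of RNA quality did not differ past the threshold in exact permutation tests. The log2 ratio of the 3' to the 5' probe set of beta-actin was 0.59 ± 0.17 in controls and 0.64 ± 0.09 after cadmium (n = 4 per group; exact two-sided permutation p = 0.629), and that of GAPDH 0.005 ± 0.062 and 0.07 ± 0.08 (n = 4 per group; exact permutation p = 0.257). The smallest p that 4 against 4 arrays allow is 0.029. All control arrays were washed and stained on module 1 of the fluidics station and all cadmium arrays on module 2, so module and treatment cannot be told apart by the design. No hybridization control transcript differed between the modules in limma (18 probe sets, largest log2 change 0.29).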

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

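The tests of single lists in other splits, of the hybridization controls and of the major histocompatibility genes were chosen only after the result was seen.

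In 7 of 156 groups of 4 arrays, 1 array lay far from the other 3, which chance alone gives in about 1 in 20 groups. In controls these were Psmc2, with a signal of 5458 in rat 4 against 5716 to 5731.6 in the others, and the oxidative phosphorylation genes Cox4i1 (9018.1 in rat 2 against 11377.9 to 11570.6) and Atp5pb (5198.2 in rat 2 against 9073.6 to 10025.8). After cadmium they were Epcam (1067.7 in rat 4 against 2361.9 to 2525.1), Hspg2 (154.6 in rat 3 against 117.3 to 120.6), Nhlrc2 (212.6 in rat 2 against 304.9 to 316.2) and the log2 ratio of the 3' to the middle probe set of beta-actin (0.46 in rat 4 against 0.331 to 0.349).

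The 336 probe sets that changed with cadmium exceeded what chance splits gave: 1 of the 35 splits of the 8 arrays into 2 groups of 4, the real one, gave as many, and the highest other, the split by chip lot, gave 4. Among the 8 splits that part the arrays of all 4 rats, which are too few for a share under 0.05, the highest other gave 0. The 18 hybridization control probe sets read only the transcripts bioB, bioC, bioD and cre, added after the treatment. Their largest absolute change plus 2 SE was 0.828, under a log2 change of 1, which argues against a module effect of 2-fold on these transcripts. They cannot exclude one on other probe sets, since module and treatment cannot be told apart by the design. For the 200 calls under 2-fold the controls decide even less. The largest control change was 0.294, its standard error reaches past the smallest call of 0.331, and the median call was 0.674.

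For the number of gene lists chance cannot be excluded: 14 of the 35 splits gave at least the real 6 lists, and the highest other gave 11. That split left most controls on 1 side and most cadmium arrays on the other, so it kept part of the treatment contrast. Its count thus cannot tell structure among the arrays from the treatment. Of the 8 splits that part all 4 rats, 2 gave as many, and the highest other gave 9. An exact permutation count over all 35 splits used the camera p of limma for each list alone, which takes the arrays as unpaired. In this exact permutation count the real split was lowest for heat shock (1 of 35 splits, camera p = 8.75e-27, lowest other 1.68e-14). The exact permutation count gave the same for immediate early genes (1 of 35, camera p = 3.5e-20, lowest other 5.67e-12). It also did for antioxidant genes (1 of 35 in the exact permutation count, camera p = 5.12e-06, lowest other 0.000787). A share of 1 of 35 is the smallest that the count allows, and it was not adjusted over the lists. The lists were also picked because they had passed in the real split, so the count cannot exclude chance for them. For proteasome genes the real split also had the lowest camera p of limma in this exact count (1 of 35; 8.49e-07), but another came close (3.54e-06) and the list did not pass with an estimated correlation (adjusted p = 0.239). Chance cannot be excluded for the unfolded protein and integrated stress list (16 of 35; 0.00676, lowest other 1.26e-17) or p53 targets (2 of 35; 0.00932, lowest other 0.000577). Only the 8 splits that part all 4 rats keep the pairing, and they are too few for a share under 0.05. There, as low a p came from 1 of 8 for each of these lists but p53 targets (2 of 8), so the many low values of the stress response list came from splits that left both arrays of at least 1 rat together.

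Between rats, 167 probe sets differed. Chip lot took a median of 33.5% of their sum of squares between rats (95% bootstrap interval over probe sets 25.7 to 39.9). The other 2 contrasts took 27.2% and 23.6%. The interval does not hold the spread between animals, and each lot held only 2 rats. These values thus cannot decide whether lot was the main source. Genes of the major histocompatibility complex, whose sequence varies between rats, were 7 of 14 among the genes that differed, against 127 of 7085 other genes (odds ratio 54.6; Fisher exact p = 2.24e-09). As 2 of these genes had prompted the test, it decides nothing, and sequence variants under the probes and differences in expression cannot be told apart. Scan day and rat cannot be told apart, and no biological explanation was tested.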

How the results depend on the processing

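Fits within a chip lot and fits of genes below the filter were chosen only after the data were seen. A change of sign counted as a reversal only where at least 1 of the 2 values passed, and as kept otherwise. By that rule, 734 of 794 values of named genes under other settings and 771 of 876 with arrays left out kept their side of the threshold, and 0 reversed. Of the 41 named genes that passed, 27 did so with each array left out. For lists, 287 of 309 and 291 of 312 values kept their side, some with a change of sign, and 2 reversed. Both were the ribosomal protein list, not passing and higher in the test, which became lower under quantile normalization (adjusted p = 0.00602; with the replicate block 0.00185). With quantile normalization 87 probe sets (59 genes) were lower, with median centring 84 (55), with the replicate block 218 (157) and at an adjusted p under 0.1 260 (196). Within chip lot 1, 40 probe sets (30 genes) were higher and 7 (1) lower, and within lot 2 75 (57) and 19 (11); 4 arrays enter each of these fits. Gene lists higher numbered 9 within lot 2 and 3 with an estimated correlation. Gene lists lower numbered 0 without the filter, with the replicate block, with an estimated correlation and with the mean of a gene's probe sets, and 3 under quantile normalization with and without the replicate block. Probe sets that differed between rats numbered 87 without the filter and 36 with no trend in the variance prior. With 1 array left out, probe sets higher ranged from 122 to 188 and lower from 49 to 125, genes higher from 85 to 135 and lower from 31 to 90, lists higher from 4 to 8 and lower from 0 to 1. With the pair of 1 rat left out of the replicate block fit, the ranges were 121 to 309, 44 to 290, 84 to 225, 26 to 203, 4 to 9 and 0 to 1, and probe sets that differed between rats ranged from 53 to 359. Of the genes named by the fixed rule and the lists, the replicate block changed the calls of Gclc and of the stress response and p53 lists and no other; it added calls of list members named after their values were seen. The cause of these shifts was not tested, fewer arrays included. Without the pair of rat 4, the counts of probe sets and genes in the replicate block fit rose. The 40% dimmest probe sets were not tested in the fit reported first, and changes near that signal are the least precise.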

Other observations

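The tests of gene lists between rats were chosen only after the result was seen, and genes in this part were chosen after their values were seen.

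Genes outside the lists made up 99 of the 145 genes that rose and 87 of the 93 that fell. The rises held the zinc finger gene Zbtb2 (log2 change 2.56), the ubiquitin ligase gene Peli1 (1.89), the growth factor gene Hbegf (1.85), the chemokine gene Cxcl3 (1.44), the histone demethylase gene Kdm6b (1.35) and the feedback inhibitor gene Errfi1 (1.34). Among the falls were the transcription factor gene Foxo3 (-0.88) and the genes of the junction and cytoskeletal linker proteins Jup (-0.73) and Plec (-0.76). Of genes with roles in RNA splicing, picked by eye and tested as no list, Clk1 (1.24) and Tra2b (0.62) were higher and Luc7l3 (-0.83), Arglu1 (-0.82) and Srsf6 (-0.66) lower. These are examples, and others such as Sf3b1, which was higher, also passed. Neither a share nor a common direction can be read from them.

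In 8 of 906 genes with at least 2 tested probe sets, 9 of 1059 pairs changed unequally in limma. Homer1 had log2 changes of 6.14 (adjusted p = 2.55e-05) and 2.40 on dimmer probe sets and 0.90 on the brightest (adjusted p = 0.0517); the control signals of the dimmer ones, 23.9 and 110.7, lay below the filter signal of 118, so the sizes of these 2 changes are imprecise. Hnrnpu (-1.96 against 0.05), Rbm39 (-1.71 against 0.33) and Hnrnpa2b1 (-1.39 against -0.02) fell on 1 probe set and not on the brightest. The cause of the unequal changes was not tested. Leaving out probe sets with several symbols, 22.1% of those that fell had no symbol, against 11% of those that rose and 12.1% of those tested (falls against rises, Fisher exact p = 0.00835, odds ratio 2.29).

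One hypothesis was that the fall of a probe set does not extend to the whole gene. In 27 genes with a fallen probe set and another tested one, which include 5 genes with 2 fallen probe sets, the other probe sets had a median log2 change of -0.264 (95% bootstrap interval -0.371 to -0.165) against a bound of -0.345, and 24 of 27 had the same sign. In 33 genes with a risen probe set the median was 0.623 (0.371 to 0.838) against a bound of 0.483, and 30 had the same sign (Fisher exact p = 1 for the share of the same sign in falls against rises). A fall of the whole gene and of single transcripts thus cannot be told apart. Dim probe sets could blur this, but with both probe sets in the brighter part 7 genes were left, with a median of -0.298 (-0.618 to -0.087; bound -0.312), which are too few to decide.

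P450 genes differed between rats more often than other genes (13 of 33, odds ratio 37.2, Fisher exact adjusted p = 2.32e-13). Rat 4 was lowest in 8 of the 13 and rat 3 in 4. The Fisher test takes genes as independent, while P450 genes had an estimated correlation of 0.248. Its p thus does not measure the spread over the 4 rats, and the same limit holds for the lists that follow. Stress response (5 of 37, Fisher exact adjusted p = 0.00621), macrophage (3 of 10, 0.00621), antioxidant (4 of 30, 0.0148) and plasma protein lists (4 of 35, 0.021) also passed. The macrophage genes did not move together. Cd68 was highest in rat 4, while Cd74 and the major histocompatibility gene RT1-Da were lowest in that rat. The stress response genes were Calr, Creld2, Hsp90b1, Pdia4 and Sdf2l1, and rat 4 was highest in each of them, unlike in most of the P450 genes. Of all 134 genes that differed, rat 4 was lowest in 59 and highest in 34.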
